A study of Mus musculus with 16 samples.

How the data were processed

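Gene expression was measured in 16 livers, each from a different male C57BL/6 mouse, on whole-transcript gene arrays. Per the labels' protocols, the mice were housed singly, started the diets at 11 weeks of age, ate them for 18 weeks and were 29 weeks old at the end. The labels describe the reference diet as high in fat and cholesterol, with 20% fructose in the drinking water, but leave the share of energy from fat unclear. In the guar gum diet, 10% of the weight was guar gum, a soluble plant fibre, in place of corn starch. Each diet had 8 livers. Frozen liver RNA of high integrity was amplified with a whole-transcript kit and labelled with biotin, per the labels' protocols. The hour at which each liver was taken, the scan batch and the food intake were not given in the sources used here.

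The authors deposited log2 values summarised per probe set with RMA (robust multi-array average, which corrects background, normalizes the arrays to a common distribution and combines the probes of a set), per the submitters' processing notes. The version of RMA and the probe set definition were not given in the sources used here. RMA compresses differences near background, so the change of a dim gene is understated, and a difference shared by all transcripts of a liver is removed by the normalization. The table held 35556 probe sets, with array medians between 4.98 and 5.06. No arrays were copies of each other, with correlations across probe sets between 0.971 and 0.989.

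Of the probe sets, 21218 were paired with exactly 1 gene in the platform annotation, 1881 with several and 12457 with none. Through their Entrez number, 21185 of the single-gene probe sets matched the RefSeq gene table of mouse assembly GRCm38.p6, and 0 symbols had to be updated. That table was used for names only, and no coordinates are printed because the build behind the array annotation was not given in the sources used here. Genes were named only from single-gene probe sets, and a gene with several was represented by the one with the highest mean. A probe set was tested if it lay above the 25th percentile of the array on at least 8 arrays, which kept 26790 and left out 8766. The kept probe sets measured 14842 named genes. The values of 539 probe sets repeated those of an earlier probe set, and 23 of these repeats are among the calls.

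Guar gum was compared with the reference diet with limma (lmFit and eBayes, version 3.58.1, in R 4.3.3) and Benjamini-Hochberg adjustment over all tested probe sets, with calls at an adjusted p under 0.05. Errors of log2 changes are standard errors of that fit. The 38 gene lists were fixed before the data were examined, and the 35 with at least 5 measured genes were tested with camera at its preset correlation of 0.01 between genes and with camera at an estimated correlation. Each list also received a score per liver, the mean of its gene-centred log2 values, compared between diets by an exact 2-sided permutation test over all 12870 assignments, with Benjamini-Hochberg adjustment over the lists. The smallest p this test can give is 0.000155. Like the tool fry, it asks whether a list differs between the diets at all, while camera compares a list with all other genes. Relations between list scores were computed within each diet, with exact permutation p-values over all pairings. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.

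On simulated data with known changes in 200 probe sets, the limma step recovered 68% of changes of 0.5 on the log2 scale, 92% of changes of 1 and 100% of changes of 2 or 4, and 4.12% of its calls were unchanged probe sets. Camera called both shifted lists and 0 of the others, but the simulated genes were independent, so this does not test the preset correlation. The permutation step gave a p under 0.05 for 3.5% of 400 null scores.

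The named genes were those with the 12 largest rises and the 12 largest falls among called genes (predicted genes and gene models without a proper name left out), up to 4 called genes per list or else the 2 with the smallest p, and further genes of lipid, bile acid and fibrosis biology named beforehand. Alternatives covered the filter, the variance prior, array weights, scaling, the replicate number as a block, covariates, a rank test, size and significance thresholds, and leaving out each liver. The sample codes carry a number that is 5 in all reference samples and 9 in all guar gum samples; if it marks a position or batch, that batch and the diet cannot be told apart.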

Results

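Liver gene expression was profiled in male mice that ate a diet labelled high in fat and cholesterol, with fructose water, either as the reference diet (n = 8) or with guar gum in place of part of the corn starch (n = 8). The comparison addresses how this fermentable fibre changes liver gene expression in a model of diet-induced fatty liver disease. Every value is a log2 RMA value per probe set from 1 array per liver, and the number of arrays limits the precision. Changes are guar gum minus reference diet.

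Livers of guar gum-fed mice had higher expression of genes of the extracellular matrix, recruited macrophages, cell division and bile ducts. Of the markers of the hepatocyte zones, 7 of 10 pericentral and 5 of 9 periportal genes fell, as did Abcg5 and Abcg8, which export sterols, the fructose carrier Slc2a5, and 4 of 22 genes of fatty acid synthesis. Camera called 24 of 35 gene lists at its preset correlation and 0 with an estimated correlation (adjusted p of at least 0.183, with 9 lists at an unadjusted p under 0.05), and fry called 25. Of 26790 probe sets tested, 1711 were higher and 1795 lower in guar gum livers, or 13.1% in all. Counted once per gene, 1173 of 14842 genes were higher and 1440 lower, of which 92 and 43 changed at least 2-fold. Counts on a list, such as 4 of 22 for fatty acid synthesis, are to be read beside these shares. Most changes were small, with a median size of 0.36 on the log2 scale. The 8 livers of each diet did not overlap for 719 probe sets, where chance gives 0.0155% of probe sets or 4.16.

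The largest rise was that of Fgf21 (Entrez gene 56636), a fasting- and stress-induced liver hormone, at 8.49 ± 0.77 in guar gum and 6.24 ± 0.51 in reference livers (mean ± SD, n = 8 each), a 4.77-fold difference (limma adjusted p = 0.00025). D17H6S56E-5, Tspan8, the matrix proteoglycan Lum, the retinol dehydrogenase Dhrs9, Igfbp1, the macrophage gene Gpnmb, Dpt, Peg10, Cib3, Scara3 and Prss8 followed, between 3.78-fold and 2.80-fold. The largest fall was that of Cyp2b9 (Entrez gene 13094), a female-biased cytochrome P450, from 9.53 ± 0.72 to 5.45 ± 1.09, or 16.9-fold lower, with all 8 guar gum livers below every reference liver (adjusted p = 4.78e-05). Gpx6 was 6.19-fold lower and Hsd3b5, a male-biased steroid dehydrogenase, 4.74-fold lower. The lipid droplet gene Cidea was 3.74-fold lower. Lrtm1, Upp2, Cyp2c54, Cyp2c37, Trhde, the clock gene Per3, Dsg1c and Mmd2 were between 3.43-fold and 2.59-fold lower. The calls of Hsd3b5 and Cidea are the least secure of these, since leaving out single livers raised the adjusted p of Hsd3b5 to as much as 0.0634 (8 of 16 fits not past the threshold) and that of Cidea to 0.0652 (9 of 16). Neither was called by an exact Wilcoxon test (adjusted p = 0.0519 and 0.0856), and with a clock score in the fit, a choice made after seeing the data, the change of Cidea went from -1.90 ± 0.56 to -0.60 ± 0.77 (adjusted p = 0.735).

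**Figure D1:**
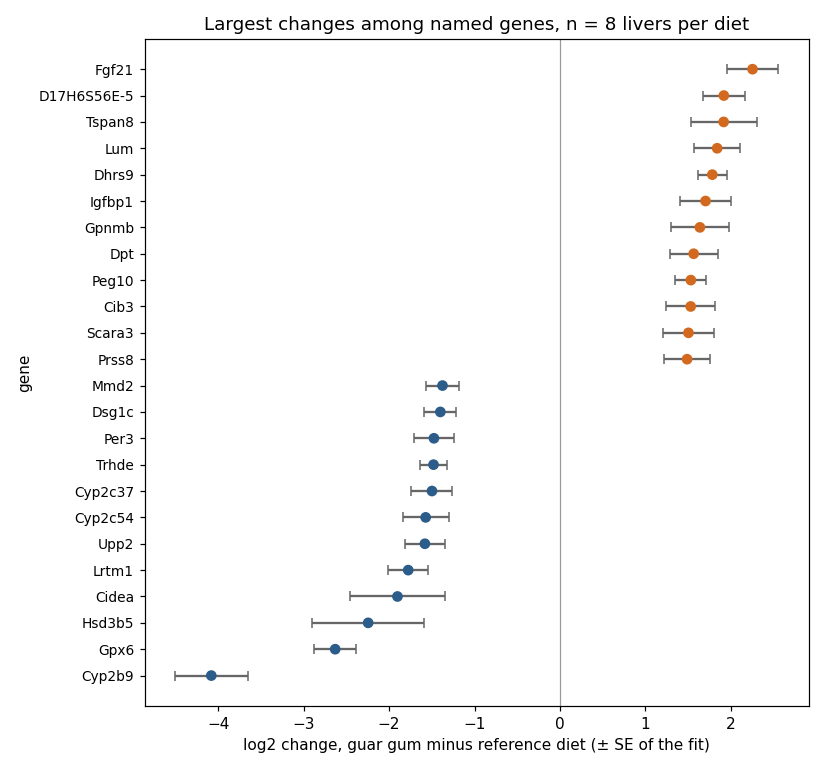
Log2 change between guar gum and reference livers (horizontal axis, points, with the standard error of the fit as bars) for the 12 largest rises and the 12 largest falls among called genes, n = 8 livers per diet. Cyp2b9 lies farthest from 0 at -4.08 and Fgf21 leads the rises at 2.25.

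Matrix genes rose together. Of 30 measured genes of the extracellular matrix list, 24 rose and 0 fell (25 and 1 adjusted over the list alone), with a median change of 0.58. The collagen gene Col1a1 was at 8.02 ± 0.37 against 6.98 ± 0.35 (n = 8 each), 2.06-fold higher (limma adjusted p = 0.000816). Col6a3 rose 2.51-fold, the matrix protease Mmp2 2.26-fold and the protease inhibitor Timp1 1.91-fold, while the change of Tgfb1 was 0.27 ± 0.10 (adjusted p = 0.0757, but 0.0466 with 1 probe set per gene, 0.0482 with single-gene probe sets only, 0.0435 without guar gum replicate 5 and 0.0497 without reference replicate 5). The list score was higher in all 8 guar gum livers than in any reference liver, by 0.67 (exact permutation adjusted p = 0.000537). Of 16 stellate cell and myofibroblast genes, 5 rose and 0 fell (7 and 0 adjusted over the list alone), among them Pdgfra (1.91-fold), Cygb (1.78-fold) and Acta2, the smooth muscle actin of activated stellate cells (1.59-fold). Their score differed by 0.25 (exact permutation adjusted p = 0.000984). Camera called both lists at its preset correlation (adjusted p = 7.91e-18 and 0.00311), with adjusted p = 0.183 and adjusted p = 0.221 with an estimated correlation.

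Markers of recruited macrophages rose while those of resident Kupffer cells, the macrophages native to the liver, went both ways. Of 19 recruited macrophage genes, 17 rose and 0 fell (17 and 0 adjusted over the list alone), with a median change of 0.88. Gpnmb, a marker of lipid-associated macrophages, was 3.11-fold higher, Ms4a7 2.75-fold, Cd63 2.32-fold and the elastase Mmp12 2.15-fold, and the general macrophage marker Cd68 was 1.63-fold higher. Mmp12 and Cd68 were not called without the 2 arrays of widest relative log expression (adjusted p = 0.055 and 0.0537). The score differed by 0.85 (exact permutation adjusted p = 0.00136). Of 11 Kupffer cell genes, 3 rose and 3 fell (3 and 4 adjusted over the list alone). Those that fell were Timd4 (2.56-fold lower), Clec4f (1.87-fold) and the dim Cd163 (1.71-fold, 3.87 against 4.64). The call of Clec4f was lost in 8 of 16 fits without 1 liver (adjusted p up to 0.0675). Of those that rose, C1qc was 1.35-fold higher, a call lost in 10 of 16 such fits (adjusted p up to 0.0838). Adgre1, shared by both kinds of macrophage, changed by 0.20 ± 0.12 (adjusted p = 0.317). Of 26 cytokines and chemokines, 7 rose and 1 fell (10 and 1 adjusted over the list alone), with Ccl3 2.03-fold, Cxcl16 1.51-fold and Il1b 1.46-fold higher, whereas Tnf (0.36 ± 0.14, adjusted p = 0.0931) and Ccl2 (0.38 ± 0.19, adjusted p = 0.221) did not pass the test. The camera calls of the macrophage and cytokine lists (adjusted p = 1.86e-13 and 0.000169) went to adjusted p = 0.183 and adjusted p = 0.332 with an estimated correlation, and the Kupffer cell list was not called (adjusted p = 0.456), although its score was lower by 0.29 (exact permutation adjusted p = 0.0308). With a clock score as a covariate, a choice made after seeing the data, the Kupffer cell score difference was -0.13 (95% interval -0.53 to 0.28).

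Genes of cell division and of the bile duct epithelium were higher as well. Of 23 cell cycle genes, 18 rose and 1 fell (18 and 1 adjusted over the list alone), with a median change of 0.71. Plk1 rose 2.57-fold, Ccna2 2.40-fold and the proliferation marker Mki67 2.38-fold, and the score of all 8 guar gum livers lay above every reference liver (difference 0.70, exact permutation adjusted p = 0.000537). Of 11 cholangiocyte genes, 7 rose and 0 fell (9 and 0 adjusted over the list alone). Cd24a was 2.53-fold higher, the epithelial adhesion molecule Epcam 2.23-fold and the keratin Krt7 1.64-fold. Epcam was lower in guar gum replicate 7 (4.05) than in any reference liver, and was not called by an exact Wilcoxon test (adjusted p = 0.0684) or without the 2 arrays of widest relative log expression (adjusted p = 0.0754). The cholangiocyte score differed by 0.62 (exact permutation adjusted p = 0.00556) and varied more in guar gum livers (SD 0.540) than in reference livers (SD 0.136). Guar gum replicates 3 and 6 had the highest scores (1.09 and 1.14), and without them, a choice made after seeing the data, the difference was 0.35 (exact permutation p = 0.00766). Camera gave adjusted p = 3.6e-13 and 5.47e-05 for these lists, and adjusted p = 0.183 and adjusted p = 0.221 with an estimated correlation. Endothelial markers moved the other way, with 0 risen and 3 fallen of 15 (0 and 5 adjusted over the list alone), among them Ehd3 and Kdr at 1.33-fold and 1.28-fold lower. The endothelial list was called by camera (adjusted p = 0.0232, with adjusted p = 0.511 with an estimated correlation) but its score difference of -0.16 was not past the threshold (exact permutation adjusted p = 0.054), the tool fry did not call it (adjusted p = 0.0702), and camera did not without guar gum replicate 2, guar gum replicate 5 or reference replicate 8 (adjusted p = 0.0741, 0.111 and 0.0524).

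**Figure D2:**
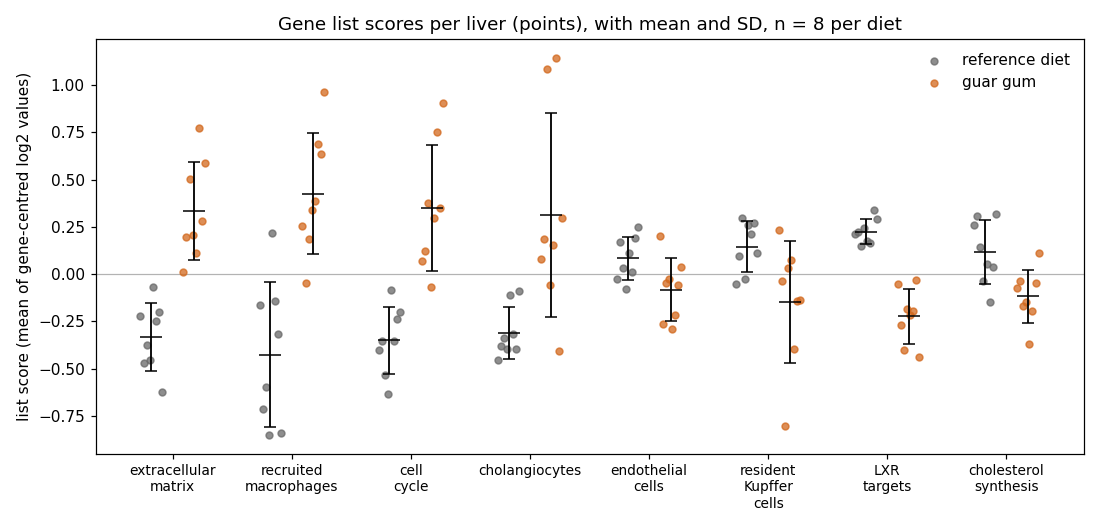
Scores of 8 gene lists (vertical axis, mean of gene-centred log2 values) in each liver (points, grey for the reference diet and orange for guar gum), with the mean and SD of each diet, n = 8. The matrix and cell cycle scores of all 8 guar gum livers lie above every reference liver, and the LXR target scores of all 8 lie below.

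Sterol and bile acid genes fell in part. Of 20 genes of cholesterol synthesis, 0 rose and 7 fell (0 and 7 adjusted over the list alone), including Stard4 (1.48-fold lower), Hsd17b7 (1.40-fold) and Tm7sf2 (1.37-fold), while Hmgcs1 (-0.11 ± 0.11, adjusted p = 0.567) and Sqle (0.37 ± 0.22, adjusted p = 0.306) did not pass. Abcg5 and Abcg8, which together export sterols into bile, were 2.19-fold and 2.16-fold lower. They belong to the LXR targets, genes of the oxysterol receptor, of which 4 of 8 fell and 0 rose (4 and 0 adjusted over the list alone), with Srebf1 1.78-fold lower and Abca1 1.16-fold lower. Of 14 genes of bile acid synthesis, 1 rose and 4 fell (1 and 6 adjusted over the list alone). Akr1d1 was 1.94-fold lower and Cyp39a1 1.94-fold higher. Cyp8b1, which directs synthesis to cholic acid, was 1.78-fold lower, a call lost in 4 of 16 fits without 1 liver (adjusted p up to 0.0552) and without the 2 arrays of widest relative log expression (adjusted p = 0.0771). Cyp7a1, the rate-limiting enzyme, was at 10.00 ± 0.52 against 10.05 ± 0.25 (n = 8 each, limma adjusted p = 0.896), and Cyp27a1 changed by -0.11 ± 0.05 (adjusted p = 0.146).

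Of 16 transporters of bile acids and sterols, 2 rose and 5 fell (3 and 10 adjusted over the list alone), with the uptake carrier Slc10a1 1.29-fold lower, the basolateral exporter subunit Slc51b 2.07-fold higher, and the bile salt pump Abcb11 at 0.21 ± 0.08 (adjusted p = 0.0875, and 0.019 without reference replicate 1). Of 11 bile acid signalling genes, 0 rose and 2 fell, Klb (1.61-fold lower) and Nr5a2 (1.29-fold lower), and adjusted over the list alone 5 fell. Nr0b2 changed by -0.38 ± 0.15 (adjusted p = 0.0993, and 0.0389 without guar gum replicate 4). Camera gave adjusted p = 0.000369 for cholesterol synthesis, 0.014 for bile acid synthesis, 0.0276 for transport, 0.0183 for signalling and 0.000804 for LXR targets. With an estimated correlation these became adjusted p = 0.327, adjusted p = 0.332, adjusted p = 0.183, adjusted p = 0.183 and adjusted p = 0.183. The exact permutation test of the scores gave adjusted p = 0.0191, 0.0135, 0.000537, 0.000537 and 0.000537 in the same order. Without members that stand on several lists, camera called neither transport (adjusted p = 0.361) nor LXR targets (adjusted p = 0.234), and the transport call was also lost with arrays centred on their medians (adjusted p = 0.0504) and with a stricter filter (adjusted p = 0.0715). Bile acid synthesis was not called without the 2 arrays of widest relative log expression (camera adjusted p = 0.0561).

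Lipogenic genes fell in part. Of 22 genes of fatty acid synthesis, 0 rose and 4 fell (1 and 4 adjusted over the list alone), namely Thrsp (2.24-fold lower), Srebf1, Acss2 (1.57-fold) and Dgat2 (1.42-fold), with Scd1 at -0.01 ± 0.04 (adjusted p = 0.914). Scd1 lay near the top of the array range (13.20 against array maxima of 13.45 to 13.61), so its value says little about a change. Of 14 genes of fructose and glucose metabolism, 8 fell and 1 rose (9 and 1 adjusted over the list alone), the fructose carrier Slc2a5 being 2.31-fold lower, Ppargc1a 1.43-fold and Gys2 1.34-fold lower, and Txnip 1.47-fold higher. The scores fell by 0.26 and 0.29 (exact permutation adjusted p = 0.0249 and 0.000537). Camera gave adjusted p = 0.00873 and 0.000221, and with an estimated correlation adjusted p = 0.439 and adjusted p = 0.183. Fatty acid oxidation and lipid droplet genes were not called as lists (adjusted p = 0.829 and 0.816), and both had a median just below 0 (-0.03 and -0.02) with an upward camera direction, while their means were 0.16 and -0.13. Among 25 oxidation genes, Fgf21 and Pdk4 (2.77-fold) rose and Ppara (1.48-fold lower) fell, which left 22 not past the test (3 rose and 3 fell adjusted over the list alone). With a clock score in the fit, the change of Ppara went from -0.565 to -0.242 (limma adjusted p = 0.167). That of Pdk4 went from 1.469 to 1.058 (adjusted p = 0.133). Of 16 lipid droplet genes, 1 rose and 3 fell (2 and 4 adjusted over the list alone), and Cidec (0.98 ± 0.37, adjusted p = 0.092, and 0.0382 without reference replicate 5) and Cd36 (-0.04 ± 0.13, adjusted p = 0.89) were not past the test.

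Hepatocyte zone markers were lower at both ends of the lobule. Of 10 pericentral genes 7 fell and 0 rose (8 and 0 adjusted over the list alone), with Rhbg, Oat, Slc1a2 and Lhpp between 1.62-fold and 1.55-fold lower, and of 9 periportal genes 5 fell and 0 rose (8 and 0 adjusted over the list alone), with the histidine lyase Hal 1.85-fold and the urea cycle enzymes Arg1 and Asl 1.47-fold and 1.43-fold lower. Of 13 genes of xenobiotic metabolism, 7 fell and 2 rose (8 and 2 adjusted over the list alone), from Cyp2b9 and Cyp2c37 to Cyp2c55, which was 1.58-fold higher but not called by an exact Wilcoxon test (adjusted p = 0.0684). The pericentral score was lower by 0.34 (exact permutation adjusted p = 0.00169), the periportal score by 0.40 and the xenobiotic score by 0.62 (adjusted p = 0.000537 each by the same exact test). Camera gave adjusted p = 0.000221, 0.000162 and 0.00496, and adjusted p = 0.183 for each with an estimated correlation. Without members shared with other lists, the xenobiotic list was not called (adjusted p = 0.13). Abundant secreted hepatocyte proteins (2 of 15 fell and 0 rose, 2 and 0 adjusted over the list alone) were not called by camera (adjusted p = 0.356), but were by fry (adjusted p = 0.0459), and their score was lower by 0.055 (exact permutation adjusted p = 0.0308).

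Of 4 measured female-biased genes, 3 fell and 0 rose, Cyp2b9, Cyp17a1 (2.48-fold lower) and Cyp2b13 (2.36-fold lower), and the same number fell adjusted over the list alone. Their score was lower by 1.84 (exact permutation adjusted p = 0.000537). Cyp17a1 was not called by an exact Wilcoxon test (adjusted p = 0.0519), without the 2 arrays of widest relative log expression (adjusted p = 0.064) or with a clock score in the fit (adjusted p = 0.266). Of 12 male-biased genes, 3 fell, among them Hsd3b5 and the growth hormone receptor Ghr (1.26-fold lower), and 2 rose, among them Socs2 (2.35-fold higher), with 3 and 3 adjusted over the list alone (camera adjusted p = 0.505). Cyp2b9 and Cyp2b13 are close paralogs, so the probe sets may share signal.

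Circadian clock genes differed between the diets in opposite directions. Of 15 measured, 8 fell and 2 rose (10 and 4 adjusted over the list alone). Per3 was 2.78-fold lower, Ciart 2.51-fold, Bhlhe41 2.46-fold and the clock output factor Tef 2.03-fold lower, while the core activators Bmal1 and Clock were 1.87-fold and 1.19-fold higher (adjusted p = 0.0439 each). The list score was lower in all 8 guar gum livers than in any reference liver (exact permutation adjusted p = 0.000537), and camera gave adjusted p = 0.00269, or adjusted p = 0.183 with an estimated correlation. The hour of sampling was not given in the sources used here. A clock score was the mean gene-centred log2 value of Per2, Per3, Ciart, Nr1d1, Nr1d2, Bhlhe41, Tef and Hlf. From it, the mean of Bmal1, Npas2, Clock and Nfil3 was subtracted. When this score was added to the fit, a choice made after seeing the data, 456 probe sets were higher and 484 lower, and 815 of the 3506 calls were kept. Of the called named genes, 70 lost the call, with a median of 98.3% of their change kept while the median standard error went from 0.15 to 0.225. The change of Gpnmb went from 1.64 ± 0.34 to 1.83 ± 0.53 (adjusted p = 0.0705), and that of the clock gene Ciart from -1.33 ± 0.28 to -0.29 ± 0.28 (adjusted p = 0.625). Ciart is itself part of the clock score, so its loss was fixed in advance.

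**Figure D3:**
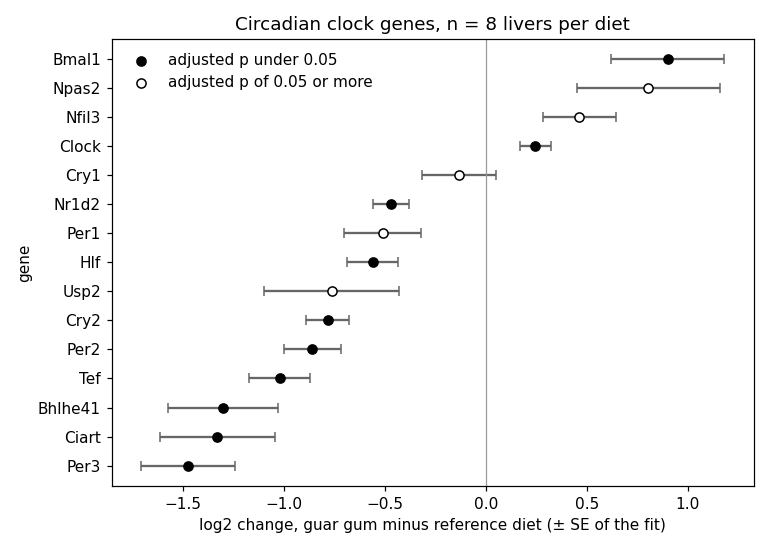
Log2 change of the 15 measured clock genes between guar gum and reference livers (horizontal axis, points, with the standard error of the fit as bars), filled where the adjusted p is under 0.05, n = 8 livers per diet. Bmal1 and Clock rose, and Per3, Ciart and Bhlhe41 fell by more than 1 on the log2 scale.

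Array quality was similar in both diets, except that the array median was slightly higher in guar gum livers (5.03 ± 0.02 against 5.00 ± 0.01, n = 8 each, exact permutation adjusted p = 0.00559). The spread of relative log expression did not differ beyond chance (difference -0.0076, exact permutation adjusted p = 0.471). With arrays centred on their medians, 35.1% of 3829 calls were higher, against 48.8% as deposited, so the balance of rises and falls depends on the scaling. Without the 2 arrays of widest relative log expression (guar gum replicate 8 and reference diet replicate 4), a choice made after seeing the data, 1058 probe sets were higher and 1305 lower, and 64.1% of all calls were kept. In 99 other splits of the 16 livers, camera at its preset correlation called a median of 11 of the 35 lists against 24 for the diets. These splits are not free of the diet: the one with most calls (21 lists) had 12 livers grouped as in the diets. High counts were not limited to such splits, since one with 10 livers grouped as in the diets called 20 lists. Splits with 8, balanced over the diets, called between 1 and 14. The diet difference also adds correlation between genes in such splits. They therefore do not measure how far the p-values for single lists may be too small, but a call at this setting alone is weak evidence.

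Within diets, 10 relations between list scores were computed. Recruited macrophage and matrix scores rose together among reference livers (Pearson r = 0.941, exact permutation p = 0.00181, adjusted p = 0.0181; Spearman rho = 0.833, exact permutation p = 0.0154, adjusted p = 0.154, n = 8). Without the 2 livers farthest from the median macrophage score, r was 0.934 (exact permutation p = 0.00833, adjusted p = 0.0833). Among guar gum livers r was 0.580 (exact permutation p = 0.133, rho = 0.571 with p = 0.151, r = 0.477 without 2 livers), and the difference between the diets was not tested. The other 8 relations had adjusted p-values of at least 0.256 by the exact permutation test of r.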

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

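Tests of the clock phase, the liver numbers, the share of hepatocytes, carry-over of other tissue, the growth hormone pattern and the count of probe sets in other splits were chosen after the results were seen. The tests of the clock covariate, the Cyp2b paralogs and the count of lists in other splits were written down before their results.

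Of 380 groups of 8 livers examined (each named gene and list score in each diet), 26 held a liver far from the other 7, where chance gives about 1 in 20. Guar gum replicate 8, whose array also had the widest relative log expression, stood apart most often. Its log2 values were low for Abcg5 (9.67), Abcg8 (9.24), Cyp27a1 (10.75) and Atp5a1 (11.16) and high for Cxcl14 (7.16), its bile acid synthesis score was -0.39 and its NRF2 score 0.39. Other guar gum livers stood apart for Peg10 (5.94, replicate 5), Ppargc1a (7.39, replicate 5), Hsd3b5 (6.69, replicate 7), Cd79a (5.31, replicate 4), Rhbg (7.04, replicate 6), Ciart (2.98, replicate 3) and Sdhb (10.37, replicate 2). The same held for the B and plasma cell score of guar gum replicate 4 (0.10) and the adipose (0.18) and erythroid (0.31) scores of replicate 2. Among reference livers, replicate 8 stood apart for Lcn2 (10.62), the fructose and glucose score (0.00) and the stellate cell score (-0.36), and replicate 6 for F9 (10.30), Pnliprp1 (5.40) and the pancreas score (1.70). Gstm3 was 11.56 in reference replicate 4, the T and NK cell score 0.35 in replicate 7 and the xenobiotic score 0.67 in replicate 3.

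The diets were compared with 99 other splits of the 16 livers into 8 and 8. Of the 100 splits, 1, the diets themselves, gave as many probe sets (3506, against 750 in the highest other, a split with 14 livers grouped as in the diets), so chance is unlikely for this count. Every other split mixes the diets within its groups, which widens its spread and lowers its count. With 100 splits, nothing rarer than 1 of 100 can be seen. For gene lists 1 of 100 splits gave as many (24, against 21 in the highest other). Chance is unlikely for that count too, though the margin is smaller. The other splits called a median of 11 lists, but they are not free of the diet and cannot measure how reliable a single list is. A single list called at the preset correlation stays weak evidence on its own, since 0 lists were called with an estimated correlation.

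The first pattern weighed is the change of clock genes. The mean of Bmal1, Npas2, Clock and Nfil3 was 0.60 higher in guar gum livers (0.603 on the log2 scale, exact permutation p = 0.0196), while the other 11 clock genes were lower by 0.84 on average (-0.84, exact permutation p = 0.000155, the smallest possible), as groups at different phases of the daily rhythm would show. Among reference livers the clock score followed the liver number (Spearman rho = 0.762, exact permutation p = 0.0368, adjusted p = 0.0735, n = 8), and among guar gum livers it did not clearly do so (rho = 0.143, exact permutation p = 0.752). The reference scores lay between -0.50 and 0.70 in replicates 1 to 4 and between 1.01 and 1.96 in replicates 5 to 8. A step between these sets and a steady trend were not told apart. A shift of sampling time and an effect of the diet on the clock cannot be told apart, because the hour of sampling was not given in the sources used here.

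The second pattern is the rise of matrix, macrophage and bile duct genes. A lower share of hepatocytes that raises all other cell types alike is argued against as the whole cause, since bile duct and endothelial scores moved apart by 0.785 (exact permutation p = 0.000777, and by 0.50 with p = 0.00167 without guar gum replicates 3 and 6, the highest in bile duct score). Both scores were picked after their changes were seen, so these p-values restate the pattern. A lower share of hepatocytes as part of the cause stays open. With the clock score as a covariate, the matrix score kept 105.1% of its difference (0.70, 95% interval 0.32 to 1.08), and the macrophage score kept 124%. Within the reference and guar gum diets, the clock score correlated weakly with the matrix score (r = 0.19 and -0.08) and the macrophage score (r = 0.34 and 0.14). The clock score itself differs between the diets, so the adjustment rests on scatter within diets and cannot exclude a difference in clock phase. Carry-over of pancreas into guar gum samples would raise a pancreas score that was in fact lower by 0.38 (-0.384, exact permutation p = 0.0127, and -0.17 with p = 0.0247 without reference replicate 6), but the adipose score rests on 3 genes (-0.05, exact permutation p = 0.304), so carry-over of that tissue stays open. An effect of guar gum on these cell types is a hypothesis that stays open beside a difference in clock phase and a batch that follows the sample code.

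The third pattern is the fall of Cyp2b9, Cyp2b13, Cyp17a1 and Hsd3b5. A female-like growth hormone pattern is argued against for Cyp2b9, Cyp2b13 and Cyp17a1, since it would raise female-biased genes, and the mean change of the 4 measured, which include these 3, was -1.84 (-1.837). For Hsd3b5 it stays open, since the other 11 male-biased genes went both ways (2 fell and 2 rose, with a median of -0.19, or -0.188). With the clock score as a covariate, the male-biased score, which includes Hsd3b5, was lower by 0.55 (-0.55, 95% interval -1.01 to -0.10). Socs2, one of the 2 that rose, went from 1.23 ± 0.26 to 0.66 ± 0.36 with it (limma adjusted p = 0.338). Cross-hybridisation that moves all Cyp2b probe sets is argued against by Cyp2b10 and Cyp2b23, whose mean change was 0.009 (0.03 ± 0.21 and -0.01 ± 0.15). Cyp2b23 is dim (3.642 in guar gum and 3.655 in reference livers), while Cyp2b10 lies just above the array medians (5.403 and 5.372). Signal of Cyp2b9 in the Cyp2b13 probe set may still account for the fall of Cyp2b13. No test here separates the remaining biological explanations.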

How the results depend on the processing

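The clock covariate, the restriction to single-gene probe sets, the fit without the 2 widest arrays and the bile duct scores without the 2 highest livers were chosen after seeing the data. None of the 131 called named genes and none of the called lists reversed direction under the alternatives run for them. Leaving out each liver in turn gave 2747 to 3672 calls (1296 to 1789 higher, 1451 to 1902 lower) and 22 to 25 lists, and 112 of 131 called named genes kept the call in all 16 such fits. The other 19 lost it at least once. Hexa (lysosome), Oit3 (endothelial), S100a8 (neutrophils) and Rps3 (ribosomal) lost it in 12 fits each, and Mogat1 (lipid droplets), C1qc and Rpl19 in 10. H2-Eb1 (MHC class II) and Insig1 (cholesterol synthesis) lost it in 8. Counts on these lists rest in part on such calls. At an adjusted p under 0.01 there were 1503 calls (681 higher, 822 lower). A test against a change of 1.2-fold left 277 (152 and 125), and requiring 1.2-fold in addition left 2523 (1337 higher and 1186 lower). These 3 settings ask more of the same values. The clock covariate left 940 calls (456 and 484), and the fit without the 2 widest arrays 1058 higher and 1305 lower. The clock score differs between the diets, so the covariate widens the errors. Of the 70 named genes that lost the call with it, 34 had a change at least as large as before and 7 a change less than 0.5 of that before. These 7 were Ciart, Bhlhe41 and Tef, whose loss was fixed in advance as parts of the clock score, and Cidea, Mogat1, Ppara and Atf4. With an estimated correlation, camera called 0 lists (9 at an unadjusted p under 0.05), while fry called 25. Of the 24 lists called at the preset correlation, 23 also passed the permutation test of the score. That test, like fry, does not compare a list with other genes, and 28 of all 38 lists passed it. Without the 2 farthest livers, 0 of the relations within diets passed the threshold (1 at an unadjusted exact permutation p under 0.05, with fewer livers). Of the 131 called named genes, 86 lost the call in the test against 1.2-fold, 70 with the clock covariate, 40 at an adjusted p under 0.01, 24 without the 2 arrays, 14 by an exact Wilcoxon test and 7 without the filter. With the clock covariate, camera no longer called transport, bile acid signalling and endothelial cells (adjusted p = 0.141, 0.0599 and 0.07) and called fatty acid oxidation and male-biased genes (adjusted p = 0.00573 and 0.0397). In a fit with that covariate, the diet difference of the fatty acid oxidation score was 0.41 and that of the male-biased score -0.55. T and NK cells were called without the filter (adjusted p = 0.0386), with the replicate block (adjusted p = 0.0346), without reference replicate 7 (adjusted p = 0.0142), without guar gum replicate 5 (adjusted p = 0.0471) and by camera on ranks (adjusted p = 0.0452), the latter also for pancreas (adjusted p = 0.044). The replicate block also called Tnf (adjusted p = 0.0431). The replicate block gave 2562 calls and kept 68.3% of the main ones (20 of the 131 named genes were not called). Across all tested probe sets, same-numbered livers did not deviate together (correlations -0.036 to 0.048), with 0 of 8 reference livers closest to its own number. Pairing of single livers was therefore not seen, but a coarser effect that follows the numbers stays open. On the second principal component (9.8% of the variance), replicates 1 to 4 were negative in both diets. Replicates 5 to 8 were positive in both, except guar gum replicate 7 (-9.4). These 2 sets of replicates are balanced over the diets, but a block of that kind was not fitted. Dim probe sets near background understate changes, and calls there are the least certain.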

Other observations

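Tests of the 3 hypotheses below were written down before their results, but the labels were made stricter afterwards: an estimated correlation had to agree, and the gene that prompted a list was left out of it.

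Further groups fixed beforehand moved by small amounts. Of 21 respiratory chain genes, 7 fell and 0 rose (10 and 0 adjusted over the list alone), among them Sdhb (1.27-fold lower) and Ndufv1 (1.19-fold lower), and the score was lower in all 8 guar gum livers than in any reference liver (difference -0.15, exact permutation adjusted p = 0.000537). Of 13 ribosomal protein genes, 5 rose and 0 fell (7 and 0 adjusted over the list alone), by at most 1.15-fold (Rpl19), and the calls of Rpl19, Rps3 and Rpl5 were lost with arrays centred on their medians. Of 17 lysosomal genes, 5 rose and 0 fell (8 and 1 adjusted over the list alone), led by the protease Ctss (1.70-fold). Camera gave adjusted p = 0.000221, 0.000369 and 0.00397 for these lists, and adjusted p = 0.221, adjusted p = 0.183 and adjusted p = 0.374 with an estimated correlation. The ribosomal and lysosomal scores were higher by 0.12 and 0.20 (exact permutation adjusted p = 0.00258 and 0.0207).

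Genes of MHC class II, neutrophils and NRF2 targets rose in part. Of 10 MHC class II genes 3 rose, with Cd74 and H2-Aa 1.45-fold and 1.39-fold higher (5 adjusted over the list alone), and of 10 neutrophil genes 4 rose, led by Csf3r at 1.63-fold (4 rose and 1 fell adjusted over the list alone). Of 14 NRF2 targets, Gstm3 (1.41-fold) and Gsta4 (1.37-fold) rose (2 adjusted over the list alone). Camera gave adjusted p = 0.00131, 0.0281 and 0.014, and adjusted p = 0.315, adjusted p = 0.183 and adjusted p = 0.345 with an estimated correlation. The scores were higher by 0.29, 0.21 and 0.17 (exact permutation adjusted p = 0.0191, 0.00236 and 0.0308). The NRF2 list was not called without the 2 arrays of widest relative log expression (camera adjusted p = 0.0502), nor the neutrophil list without guar gum replicate 2 (camera adjusted p = 0.0577). Lists of T and NK cells (Il7r rose 2.16-fold, 1 of 18), B and plasma cells (0 of 8 by limma at the adjusted threshold), interferon response (Oasl1 fell, 1 of 19), acute phase (Lcn2 rose 1.51-fold and Crp fell, of 19) and unfolded protein response (Atf3 and Atf4 rose and Edem1 fell, of 18) were not called by camera, with adjusted p = 0.0977, 0.39, 0.475, 0.517 and 0.225. The T and NK cell list was called without reference replicate 7 (camera adjusted p = 0.0142) and without guar gum replicate 5 (camera adjusted p = 0.0471). Adjusted over the list alone, the counts of these lists did not change. The B and plasma cell score was nevertheless lower by 0.088, with 7 of 8 guar gum livers below every reference liver (exact permutation adjusted p = 0.0159), and fry called that list (adjusted p = 0.0074). The scores of the other 4 lists were not past the threshold (exact permutation adjusted p of at least 0.0848). Of 6 pancreas, 3 adipose and 4 erythroid genes, 0 passed limma's adjusted threshold. The pancreas list was not called by camera (adjusted p = 0.102), while its score was lower by 0.38 (exact permutation adjusted p = 0.0211). Much of that came from reference replicate 6 (score 1.70), without which the difference was -0.17 (exact permutation p = 0.0247). The pancreas genes Cela3b (3.62 against 4.05) and Pnliprp1 (3.42 against 3.95) were dim, so this difference is uncertain.

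As hypotheses, the rises of Fgf21 and Atf3, of the cell cycle inhibitor Cdkn1a and of Ankrd1, all picked after their values were seen, may reflect activity of ATF4, p53 and YAP. Of 16 ATF4 targets 4 rose and 1 fell, with a median of 0.16 (0.164, camera p = 0.0282, p = 0.255 with an estimated correlation). Without Cdkn1a, 5 of 13 p53 targets rose and 0 fell, with a median of 0.30 (0.305, camera p = 0.000301, p = 0.114 with an estimated correlation). Without Ankrd1, 5 of 12 YAP targets rose and 0 fell, with a median of 0.22 (0.223, camera p = 0.000735, p = 0.0555 with an estimated correlation). The list scores differed in the same direction (exact permutation p = 0.0494, 0.00544 and 0.000777, n = 8 per diet). Each list met the threshold at the preset correlation, at which other splits of the livers also gave calls for the fixed lists. None met it at an estimated correlation, so the 3 hypotheses stay open.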
